A study of Mus musculus with 2 samples.

How the data were processed

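Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts open chromatin and inserts sequencing adapters there, in 2 samples of unstimulated mouse dendritic cells. Both samples belong to 1 group and carry the replicate numbers 1 and 2, and the labels do not say whether they came from separate cultures. The labels describe the cells as a CD8-positive dendritic cell line, give the spleen as the source and name bone marrow-derived macrophages in the text on lysis, and these descriptions are not reconciled in the sources used here. The series text also describes cells stimulated with pIC, a synthetic double-stranded RNA, or with CpG DNA, and such samples were not analysed here.

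The data are the authors' annotated peak lists, 1 per sample, on the mouse genome build mm10. The submitters' processing notes name BWA 0.7.10, SAMtools 0.1.19, MACS2 (version not given) and HOMER 4.2. Duplicate removal, the shift of reads for the Tn5 cut, the removal of mitochondrial reads or excluded regions and the thresholds of the peak calls are not given in the sources used here. The names of the lists carry abbreviations, in part different for each sample, which the labels do not explain and which were not interpreted, so a filter on regions or a difference in input between the samples stays possible. The peak score deposited by the authors was read as a -log10 p-value or q-value per peak. The header says only that it is a score, and the unit was inferred from the lowest score, which was the -log10 of 0.05 in both lists, and from the widening steps between the commonest scores. The score grows with sequencing depth and was not normalized between samples, so it served only to rank, filter or describe peaks within their own list. The distance to the transcription start site (TSS) is in bp from the peak centre to the nearest RefSeq TSS, per the file headers. The lists hold no read counts, so the depth is unknown, and a region without a peak is one that the peak caller did not report, which does not show closed chromatin.

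Overlapping intervals within a list were to be merged, but none overlapped, the closest neighbours being 44 bp apart. A peak was called shared when it overlapped a peak of the other replicate by 1 bp or more. The overlap was set beside 100 random placements of the other list on the same chromosomes. Score ranks of shared peaks were compared by Spearman's rho across peaks, which are not independent replicates, so no p-value is given. A gene had a promoter peak when a peak with that gene as its nearest lay within 1 kb of the TSS in both replicates. Of the 9700 genes with a promoter peak in both replicates, 100 had no pair of promoter peaks that overlapped between the replicates, among them the list members Cd8a and Psmb9. The peaks near a gene were the shared peaks within 50 kb for which it was the nearest gene, averaged over both replicates.

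The genes tested were the 21027 protein-coding genes on the autosomes and the X and Y chromosomes in a RefSeq gene table of assembly GRCm38.p6, the same build, including genes never named in a peak list. The plan's wording left open whether genes without any peak belonged to this set, and the wider set was taken because a gene without a peak could have had one. Of the 17696 genes named in either list, 17647 were matched to the table. The 14 gene lists were fixed before the data were examined, as were the tests, the genes named below and all alternatives except those named as added later. They comprise markers of type 1 (CD8-positive), type 2 and plasmacytoid dendritic cells, macrophages and monocytes, B cells, T and natural killer cells, neutrophils, erythroid cells and megakaryocytes, and tissues outside the blood, and also inflammatory, antiviral, pathogen-sensing, antigen-presentation and housekeeping genes. Emr1, Mb21d1 and Tmem173 were matched by older symbols, and Mx1, Mx2 and Cxcl11, which are not protein-coding genes with a curated transcript in the table, were left out, so that 41 of 44 antiviral genes were tested. The type 1 list shares Tlr3, Tlr11 and Tlr12, and the plasmacytoid list Tlr7 and Tlr9, with the pathogen-sensing list.

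The named genes were 9 fixed in advance (Tlr3, Tlr9, Irf8, Batf3, Ifnb1, Il12b, Il6, Tnf and Cxcl10). Added to these were the 8 inflammatory and 8 antiviral genes with the highest mean percentile of promoter peak score, and up to 12 of each, in alphabetical order, without a promoter peak in either replicate. From each other list came the 4 highest and up to 4 without. Over all genes, the 10 with the most shared peaks and the 5 highest distal shared peaks were taken. Some genes that this rule picks are not reported here. Other genes in the text were picked after their values were seen.

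Promoter peak shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family: 14 lists against all other genes, the type 1 list against 8 other cell type lists, and 2 inducible lists against housekeeping genes. The threshold was an adjusted p of 0.05. Shares carry 95% Wilson intervals, and differences of shares carry intervals by Newcombe's method. Peaks per gene were compared by a two-sided permutation test with 100000 resamples of list membership. Genes were the units of these tests, so the p-values describe these 2 libraries and not the spread between cultures, and all intervals cover counting error only. Promoter peak shares were recomputed with other promoter windows, stricter score filters, peaks in either replicate, each replicate alone, start sites from the reference table and all genes named in either peak list in place of the coding genes, which drops genes for lacking peaks, adds genes outside the coding set and is not counted among the alternatives between gene lists. Peaks per gene were recomputed with other distances, stricter score filters, each replicate alone and distal peaks only, the overlap and rank correlation with a stricter overlap and with subsets of peaks, and the share near a TSS with other distances, score filters and each replicate alone. Leaving out members of several lists, and leaving out peaks in repeats, were added after seeing the data.

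The procedures were tested on simulated data. Overlap planted at 70.66% among 20000 intervals was recovered as 70.66%. With the 85 inflammatory and antiviral genes, the share test passed the threshold in 5.5% of 200 simulations without a difference, in 51.5% with a difference of 20 points and in 79% with 30 points. With the 46 type 1 dendritic cell and macrophage genes, a difference of 30 points passed an unadjusted threshold in 57.5% of simulations. A difference of 2 peaks per gene passed in 71.5%. The planned motif counts and promoter CpG contents need the genome sequence and were not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.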

Results

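Open chromatin was mapped in 2 ATAC-seq samples of unstimulated mouse cells that the labels describe mainly as CD8-positive dendritic cells, although the text on lysis names macrophages. CD8-positive, or type 1 conventional, dendritic cells present antigen taken up from other cells on MHC class I. They sense double-stranded RNA, such as pIC, through Tlr3 and CpG DNA through Tlr9. The series sets the inflammatory program of dendritic cells against their antiviral program, and the samples described here show the state of the chromatin before any stimulus. Replicate 1 had 71616 peaks covering 14.8 Mb, with a median width of 165 bp, and replicate 2 had 75124 peaks covering 16.5 Mb, with a median width of 172 bp. Read depth is unknown for both samples.

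Both replicates opened largely the same regions. Of the peaks of replicate 1, 61273 (85.6%, Wilson 95% interval 85.3 to 85.8) overlapped a peak of replicate 2, and of those of replicate 2, 59907 (79.7%, 79.5 to 80) overlapped a peak of replicate 1. Random placements gave means of 1.23% and 1.18%. Peaks within 1 kb of a TSS made up 23.6% ± 0.773 (SD, n = 2) of the lists. Introns held 39.8% ± 0.0574 of the peaks and intergenic sequence held 37.3% ± 0.631 (SD, n = 2).

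Shared peaks lay near start sites more often than peaks of a single replicate. In replicate 1, 25.5% (25.2 to 25.8) of shared and 15.8% (15.1 to 16.5) of single peaks lay within 1 kb of a TSS, and in replicate 2 the shares were 24.7% (24.4 to 25) and 16.3% (15.8 to 16.9). The gap was smaller among low-scoring peaks: in the lowest 20% by score, which held most single peaks, the shares were 20.1% and 16.8% in replicate 1 and 23% and 20.4% in replicate 2. Single peaks were narrow, with median widths of 93 and 102 bp in replicates 1 and 2 against 183 and 201 bp for shared peaks. By the authors' score, which is used within each list only, 53.0% of the lowest decile of peaks in replicate 1 and 39.1% in replicate 2 were shared, and 100% of the highest decile in both. Across the 61273 shared peaks of replicate 1, score ranks had a Spearman's rho of 0.756.

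**Figure D1:**
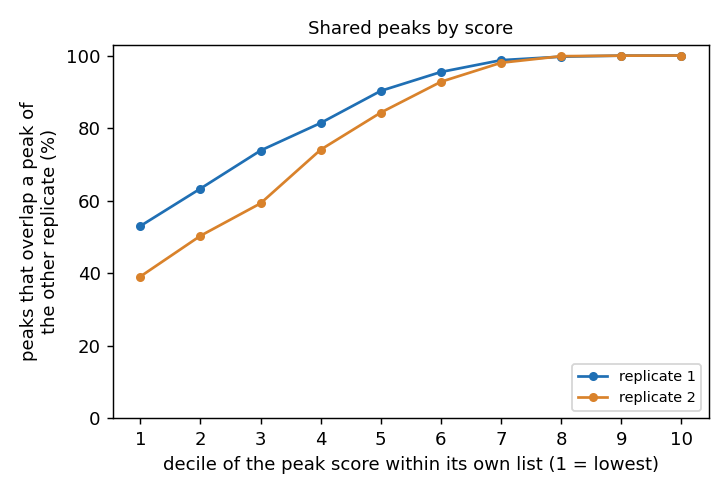
Percentage of peaks that overlap a peak of the other replicate (vertical axis) by decile of the peak score within its own list (horizontal axis, 1 is the lowest), with 1 line per replicate. The share is 53.0% and 39.1% in the lowest decile of replicates 1 and 2 and reaches 100% in the highest.

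The promoters of genes on the type 1 dendritic cell list were mostly open. Of 26 such genes, 22 (84.6%, 66.5 to 93.9) had a promoter peak in both replicates, against 46.1% of all other coding genes. Itgax, which encodes CD11c, had the highest promoter peak of the list by score percentile (chromosome 7, 128128846 to 128129613 in replicate 1, annotated as promoter), with scores of 39.0 and 46.1. Flt3, the receptor of a growth factor that drives dendritic cell development, followed with a peak in its first exon (5' UTR; chromosome 5, 147400239 to 147400498), then Wdfy4, needed for cross-presentation, and Ly75, an endocytic receptor also called DEC-205. Irf8 and Batf3 encode transcription factors that these cells need to develop. Irf8 had a promoter peak on chromosome 8 (120736162 to 120736436) and 12 shared peaks within 50 kb, and Batf3 had weaker promoter peaks, the highest of which had scores of 3.04 and 7.41 and lay at different places in the 2 replicates, but 16 shared peaks within 50 kb. No promoter peak was found in either replicate at Xcr1, Itgae or Gpr141, whose nearest peaks in replicate 1 lay 1319, 2540 and 4052 bp from the TSS. Clec9a had one in replicate 2 only. Some members of the list, such as Flt3, are not specific to type 1 cells. Neither the share of the list nor its excess over other lists thus shows type 1 identity by itself.

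The share of the type 1 list exceeded that of other genes by 38.5 points (20.4 to 47.8; Fisher's exact test, adjusted p = 0.000400, 14 lists), and by 21.4 points, no longer past the threshold, with only the 20000 highest peaks (adjusted p over 10 alternatives 7.02e-05 to 0.108). It also exceeded the share of each of the 8 other cell type lists, although promoter type, which may set the share, was not compared. By Fisher's exact test, the differences were 34.6 points against both plasmacytoid and type 2 dendritic cell genes (5.16 to 59.6; adjusted p = 0.0334 for each) and 29.6 points against macrophage and monocyte genes (3.21 to 52.4; adjusted p = 0.0464). By the same exact test they reached 63.2 points against B cell genes (adjusted p = 0.000283), 71.0 against T and natural killer cell genes (5.06e-06), 77.5 against neutrophil genes (6.37e-06), 59.6 against erythroid and megakaryocyte genes (0.00102) and 74.6 against genes of tissues outside the blood (4.28e-06). These 5 calls held in 9 of 9 alternatives, although with the 20000 highest peaks the differences were 39.0, 37.1, 46.2, 46.2 and 41.2 points. The calls against plasmacytoid, type 2 and macrophage genes held in 1, 4 and 4 of 9 alternatives (adjusted p 0.0444 to 0.329, 0.00583 to 0.236 and 0.0142 to 0.250), and with replicate 1 alone the differences from plasmacytoid and macrophage genes, 27.5 and 29.6 points, no longer passed.

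Genes of the neighbouring myeloid cell types were open in part. Among plasmacytoid dendritic cell genes 7 of 14 had a promoter peak in both replicates, the highest at Bst2, Tlr9, Tcf4 and Siglech, while Ccr9, Cox6a2, Ly6d and Spib had none. Among type 2 dendritic cell genes 7 of 14 did, led by Clec12a, Irf4, Notch2 and Klf4, while Cd209a, Cx3cr1, Dtx1 and Esam had none. Among macrophage and monocyte genes 11 of 20 did. Apoe, which encodes a lipid carrier, had scores of 35.4 and 42.0 (chromosome 7, 19699528 to 19699917), and the complement genes C1qa and C1qc also had promoter peaks, while Ccr2, Cd163, Emr1 and Marco had none. The shares were 50%, 50% and 55% (34.2 to 74.2 for macrophages). None of these lists differed from other genes by Fisher's exact test (adjusted p = 0.795, 0.795 and 0.587), and the sign of each difference turned in some alternatives.

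Markers of lymphocytes, neutrophils, red cells and other tissues were mostly without promoter peaks. The share was 13.6% (3 of 22) for T and natural killer cell genes, where Il7r, Cd5 and Klrk1 had peaks and Bcl11b, Cd247, Cd3d and Cd3e had none. It was 7.14% (1 of 14) for neutrophil genes, where Cebpe had a peak and Camp, Csf3r, Cxcr2 and Elane had none, and 10% (2 of 20) for tissues outside the blood, where Pax6 and Col1a1 had peaks and Afp, Alb, Cdh5 and Cdx2 had none. These 3 shares were lower than in other genes by Fisher's exact test (adjusted p = 0.00415, 0.00453 and 0.00248). B cell genes, with 3 of 14 (21.4%; Blnk, Ebf1 and Ms4a1, but not Blk, Cd79a or Cd79b), and erythroid and megakaryocyte genes, with 3 of 12 (25%; Itga2b, Pf4 and Epor, but not Alas2, Gata1, Gp1ba or Hba-a1), did not pass the exact test (adjusted p = 0.146 and 0.204). A window of 2.5 kb, or only the 20000 highest peaks, ended the 3 calls, peaks in either replicate ended that of T and natural killer cells, and B cell genes passed with a window of 500 bp and erythroid genes with peaks at or above the median score.

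**Figure D2:**
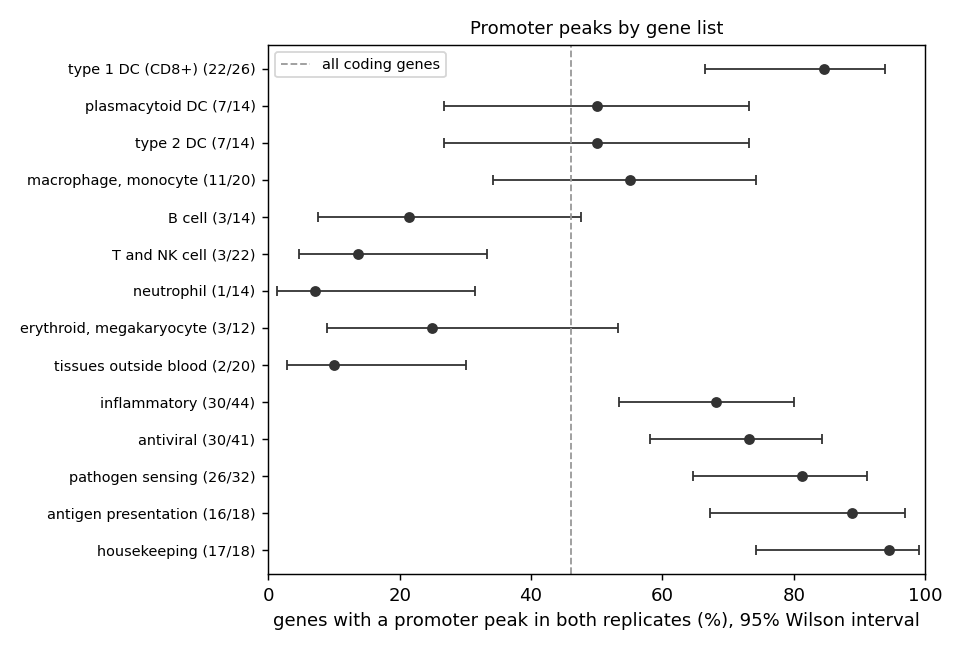
Percentage of the genes of each list with a promoter peak in both replicates (horizontal axis). Points are shares, bars are 95% Wilson intervals, counts stand beside the list names, and the dashed line marks all coding genes at 46.1%. The type 1 dendritic cell list stands at 84.6%, the macrophage list at 55% and the neutrophil list at 7.14%.

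Most inflammatory and most antiviral genes had open promoters before any stimulus. Of 44 inflammatory genes, 30 (68.2%, 53.4 to 80) had a promoter peak in both replicates, and of 41 antiviral genes, 30 (73.2%, 58.1 to 84.3). Tnf, the cytokine gene, led the inflammatory list (chromosome 17, 35201926 to 35202166, promoter; scores 27.1 and 32.5). It was followed by the chemokine gene Ccl22, the NF-kB regulators Nfkbiz, Relb, Tnfaip3 and Nfkb2, and the costimulatory genes Cd40 and Cd86. Il6 (chromosome 5, 30013143 to 30013345; scores 14.99 and 19.7) and Il12b (chromosome 11, 44399051 to 44399184; scores 8.99 and 17.1) also had promoter peaks. Those of Il12b lay near the edge of the 1 kb window, at -946 and -922 bp from the TSS in replicates 1 and 2. A closer peak, 257 bp from the TSS, was found in replicate 2 only. Gbp3, an interferon-inducible GTPase gene, led the antiviral list with a peak in its first intron (chromosome 3, 142560422 to 142560879; scores 29.1 and 45.1). Stat2 and Irf9, which encode parts of the interferon-activated factor ISGF3, the RNA sensor gene Ifih1, and Trim21, Ifit2, Tnfsf10 and Eif2ak2 followed, and Cxcl10 had its highest promoter peaks at different places, -92 bp from the TSS in replicate 1 (score 15.7) and -803 bp in replicate 2 (score 15.6).

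A smaller part of both lists had no promoter peak assigned in either replicate. These were 12 inflammatory genes (Ccl3, Ccl4, Ccr7, Cxcl1, Il10, Il12a, Il1b, Lcn2, Nos2, Ptgs2, Saa3 and Traf1) and 9 antiviral genes (Ccl5, Ddx58, Ifi44, Ifit1, Ifnb1, Irf7, Oas1a, Oasl1 and Rsad2). At Ifit1 a peak lay at the start site in both replicates but was assigned to the adjacent gene Ifit1bl2, so Ifit1 counts as open when start sites come from the reference table. The untested Cxcl11 had none either. Several of them had shared peaks outside the promoter window: Il10 had 11 within 50 kb, Il12a 9 and Il1b 8.5 on average. At Ifnb1, which encodes interferon beta, the nearest peak lay 6986 bp from the TSS in replicate 1 and 6987 bp in replicate 2. No peak lay within 50 kb of Lcn2, Nos2, Ifi44, Oas1a or Rsad2 with that gene as its nearest. The nearest peaks in replicate 1 of Irf7 (1199 bp from the TSS), Il10 (1282 bp), Traf1 (1303 bp) and Saa3 (1492 bp) lay just outside the window.

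The promoter share of inflammatory genes minus that of antiviral genes was -4.99 points (-23.5 to 14.2; Fisher's exact test, p = 0.642), so no difference was detected with these numbers of genes. Over 8 alternatives the difference ran from -15.7 points, with peaks at or above the median score, to 1.66 points, with a window of 2.5 kb, and none passed (Fisher's exact p = 0.191 to 1). Both shares were higher than in other genes, by 22.1 points (7.34 to 33.9; adjusted p = 0.00582) and 27.1 points (11.97 to 38.2; Fisher's exact test, adjusted p = 0.00214). The 20000 highest peaks alone ended both calls, and the call of the inflammatory list also ended with peaks at or above the median score and with all genes named in a peak list in place of the coding genes, a set that leaves out genes without peaks and adds genes outside the coding set (adjusted p over its alternatives 0.000648 to 0.617, and 0.000577 to 0.108 for antiviral genes).

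Inflammatory genes had more open regions around them than antiviral genes. On average, 4.97 shared peaks (SD between genes 3.77) lay within 50 kb of the 44 inflammatory genes and nearest to them, against 2.66 (SD 1.92) for the 41 antiviral genes. Fos, with 16.5, had the most of the inflammatory list, followed by Nfkbia with 12, Il10 with 11, Nfkbiz with 10.5 and Il6 with 10. Tnf, in contrast, had only its promoter peak, and the antiviral genes Stat2 and Trim21 had 1 each. The lists overlapped: among antiviral genes Trim25 had the most, with 8, followed by Usp18 with 6.5, and 4 genes of each list had none. The mean was 6.83 for type 1 dendritic cell genes, 4.22 for housekeeping genes and 2.11 over all coding genes. The difference between the inflammatory and antiviral lists was 2.31 peaks per gene (permutation test, p = 0.000450) and passed in 7 of 7 alternatives, at 0.567 to 2.91 peaks per gene, the lowest with the 20000 highest peaks.

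**Figure D3:**
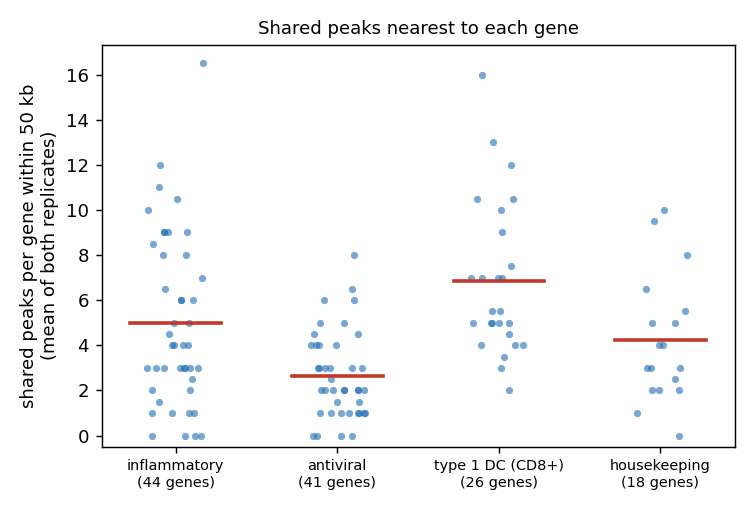
Shared peaks within 50 kb for which the gene is the nearest, averaged over both replicates (vertical axis), for 4 gene lists. Each point is a gene, spread sideways for visibility, and the red line is the list mean, 4.97 for inflammatory, 2.66 for antiviral, 6.83 for type 1 dendritic cell and 4.22 for housekeeping genes.

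**Figure D4:**
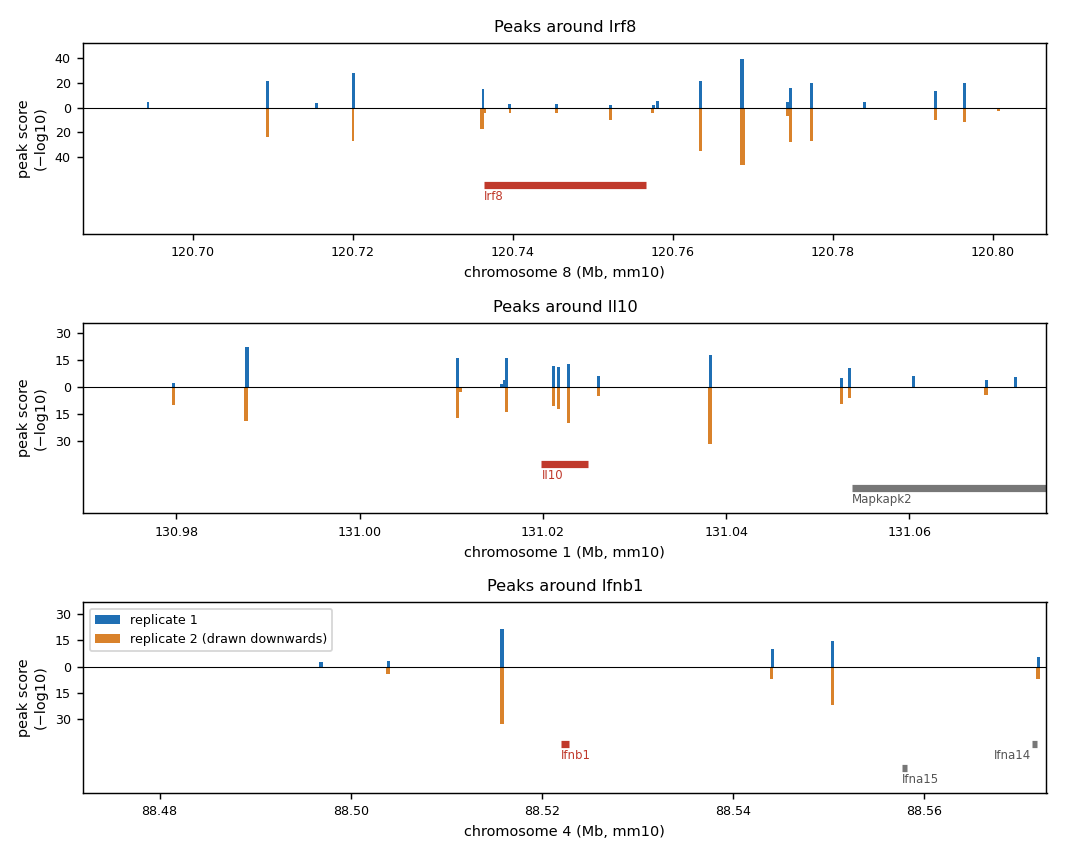
Peaks within 50 kb of Irf8, Il10 and Ifnb1 on mm10 (horizontal axes, Mb), with bar height giving the authors' peak score (-log10) in replicate 1 upwards and in replicate 2 downwards, and gene bodies drawn beneath. The Irf8 region holds 18 and 16 peaks, the Il10 region 16 and 13 and the Ifnb1 region 6 and 5.

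Genes for sensing microbes and for presenting antigen were open in most cases, as were housekeeping genes. Of 32 sensing genes, 26 (81.2%, 64.7 to 91.1) had a promoter peak, the highest at Tlr4, Irak4, Ticam1 and Traf6, while Ikbke, Irf3, Ticam2 and Tlr13 were among the 6 without. The nearest peaks of Irf3 lay just outside the window, 1124 and 1146 bp from the TSS in replicates 1 and 2. Tlr3 had its highest promoter peaks on chromosome 8 at 45410923 to 45411187 in replicate 1 and, in its first intron, at 45410166 to 45410488 in replicate 2, with scores of 17.9 and 25.2. Its closest peaks lay 215 and 212 bp from the TSS in replicates 1 and 2, and it had promoter peaks that overlapped between them. Tlr9 had peaks at its TSS on chromosome 9 (106222471 to 106222728) with scores of 23.8 and 25.4. Of 18 presentation genes, 16 (88.9%, 67.2 to 96.9) had one, led by H2-K1, H2-D1, B2m and H2-Eb1. Nlrc5, a regulator of MHC class I, had none assigned. With start sites from the reference table Nlrc5 could not be resolved and was dropped rather than counted as without a peak. Of 18 housekeeping genes, 17 (94.4%, 74.2 to 99.0) had one, led by Tbp, Rplp0, Tfrc and Gusb, and Rpl13a had none.

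These 3 shares were higher than in other genes by Fisher's exact test (adjusted p = 0.000400, 0.000770 and 0.000400). With only the 20000 highest peaks, 1 of the 9 lists that had differed from other genes still did, antigen presentation. Set beside housekeeping genes, the share of inflammatory genes differed by -26.3 points (-41.7 to -2.86) and that of antiviral genes by -21.3 points (-37.1 to 1.79), and neither passed Fisher's exact test (adjusted p = 0.0836 for both). Over 8 alternatives, none of which passed, the differences ran from -30.1 to -14.9 points and from -21.3 to -5.42 points. Both passed Fisher's exact test only with genes named in a peak list in place of the coding genes (-28.6 and -22.0 points, adjusted p = 0.0251 and 0.0469). That set leaves out genes without peaks and is not counted among the 8.

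Over all genes, the most shared peaks within 50 kb were found at Sgms1, a sphingomyelin synthase gene on chromosome 19, with 26.5 on average over the replicates. Cmip had 25, Asap1 and Dennd1b had 23.5 each, Hpcal1 had 21.5, and Rbpj, which encodes the DNA-binding factor of Notch signalling, had 20.5. Fbxw7 and Plekha2 had 20 each, and Phc2 and Sgk1 had 19.5 each. The highest distal peak of both lists was intergenic (chromosome 5, 60042690 to 60043101), at -56893 bp from the TSS of 4933402J10Rik, with scores of 121.5 and 137.1. The next 4 lay in telomere-type simple repeats on chromosomes 11, 16, 1 and 19 (121982341 to 121982567, 98107491 to 98107789, 195371688 to 195371992 and 61331258 to 61331584). Outside repeats, the next was in intron 1 of Large (chromosome 8, 73319618 to 73319778), with scores of 65.5 and 71.1, and was picked after its values were seen. Its widths, 161 and 156 bp in replicates 1 and 2, were smaller than those of the 4 repeat peaks. A mapping artifact was not tested there or at the highest peak.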

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

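The test of peak widths was chosen before its result was seen, after the repeats had been noticed among the highest peaks. Kinds of sequence that no comparison is about held peaks beyond the 3 that a count of 0 would allow. Telomere-type repeats held 74 peaks in replicate 1 and 75 in replicate 2, ribosomal RNA repeats held 50 and 49, and the mitochondrial genome held 5 in replicate 1.

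Telomere-type repeats were over-represented among the highest peaks, with 17 of the 100 highest in replicate 1 and 11 in replicate 2, against 0.103% and 0.0998% of all peaks. A candidate explanation is that reads from many repeat copies stacked on the few copies in the assembly. Peaks of that kind would be narrow for their score, and the median width of the telomere-type peaks lay at percentile 3.75 in replicate 1 and 2 in replicate 2 among the 200 other peaks nearest in score. That is what stacked reads predict, but mapping qualities were not used here, and open chromatin in such tracts stays untested. No biological explanation was tested, since the design has 1 group.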

How the results depend on the processing

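Leaving out members of several lists or peaks in repeats was chosen after seeing the data. Of all recomputed values, 221 kept their direction and side of the threshold or stayed within the spread, 34 no longer passed, 4 newly passed, 9 turned in direction and 10 moved. Of the 221, 17 could hardly differ, since no peaks were merged or no member of the list stood on another. The excess of peaks per gene at inflammatory over antiviral genes passed in 7 of 7 other alternatives, and the type 1 dendritic cell list exceeded the B, T and natural killer cell, neutrophil, erythroid and other tissue lists in 9 of 9, by 37.1 to 81.3 points. No paired analysis was possible because there is 1 group. Motif and CpG alternatives were not run for lack of sequence, and peaks as listed changed nothing. Taking the 17696 genes named in a peak list in place of the 21027 coding genes changes 2 things, since it drops genes for lacking peaks and, with only 15763 of the named genes in the coding set, adds others. Its calls between lists thus select in part on the outcome and are left out of the counts of alternatives per comparison, though not of the totals above. Why a value changed between settings was not tested, also where fewer peaks or genes entered. Values are differences of promoter share in points.

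Inflammatory minus antiviral turned to 1.66 with 2.5 kb and was -15.7 with the median and -9.48 with 20000 peaks, none past the threshold. Against other genes, plasmacytoid genes turned to -1.53 (median score or higher), -3.03 (reference start sites) and -7.79 (genes named), type 2 genes to -0.721 (500 bp), -8.68 (median) and -3.38 (20000 highest peaks), and macrophage genes to -3.58 (500 bp) and -2.25 (median), with none past the threshold in the main or these settings. The 20000 highest peaks ended the calls of type 1 genes (21.4), T and natural killer cells (-15.7), neutrophils (-24.8), other tissues (-19.8), inflammatory (4.75), antiviral (14.2), sensing (12.7) and housekeeping genes (19.7). With 2.5 kb, T and natural killer cells (-22.5), neutrophils (-28.4) and other tissues (-24.8) no longer passed, nor did T and natural killer cells with either replicate (-23.0), or inflammatory genes with the median (10.5) or genes named (13.7). B cell genes newly passed with 500 bp (-29.3) and erythroid genes with the median (-37.3).

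Type 1 minus plasmacytoid genes no longer passed with 500 bp (26.9), 2.5 kb (20.9), the median (29.7), 20000 peaks (17.6), either replicate (24.2), reference start sites (35.4) or members of several lists left out (32.6), and gave 27.5 to 31.3 with single replicates, failing with replicate 1 alone. Type 1 minus type 2 genes failed with the median (36.8), 20000 peaks (24.7), either replicate (31.3), reference start sites (28.3), genes named (26.3) and several lists (32.6). Type 1 minus macrophage genes failed with the median (30.4), 20000 peaks (21.2), reference start sites (25.6), genes named (26.7) and several lists (27.6), and gave 29.6 to 33.5 with single replicates, failing with replicate 1 alone. Inflammatory and antiviral minus housekeeping genes newly passed with genes named (-28.6 and -22.0), where the members of all 3 lists change, and ran from -30.1 to -14.9 and from -21.3 to -5.42 in 8 other alternatives.

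Overlap moved to 73.2% and 69.8% with 50% reciprocal overlap, to 80.2% in replicate 1 with 20000 peaks and to 80.6% in replicate 2 with the median. The rank correlation of peak scores moved to 0.817 with reciprocal overlap and 0.743 for distal peaks. The share near a TSS moved to 18.7% (500 bp), 28.9% (2.5 kb), 28.3% (median) and 33.7% (20000 peaks). Unknown depth limits what a missing peak shows.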

Other observations

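The gene families and sex chromosome values below, and the test of whether the samples were macrophages, were chosen only after the results were seen. Among families of interferon-induced genes, 5 of 6 Ifit genes, 8 of 10 Gbp genes and 3 of 11 Oas genes had a promoter peak in both replicates, differences that were not tested. The remaining Ifit gene, Ifit1, has a peak at its start site that was assigned to Ifit1bl2. The interferon genes themselves were almost all without one, with Ifna14 as the only one of 27. Toll-like receptor genes had 9 of 12, Stat genes 6 of 7 and Irf genes 6 of 9, while chemokine genes had 10 of 38 and chemokine receptor genes 3 of 18 (Ccr1, Cxcr3 and Cxcr4). Interleukin genes, counted together with the receptor genes Il7r, Il9r, Il21r and Il23r, had 8 of 37, with Il7r among the 8. Families used in other tissues had few or none: 16 of 1108 olfactory receptor genes, 0 of 355 vomeronasal receptor genes, 0 of 53 keratin genes, 0 of 42 beta-defensin genes and 6 of 39 Hox genes. Ribosomal protein genes had 58 of 72 and Psm genes, most of them for proteasome subunits, 34 of 40.

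On the Y chromosome, 0 of 78 coding genes had a promoter peak in both replicates. Ddx3y, Eif2s3y, Kdm5d and Uty, which are broadly expressed in males, had no peak assigned to them within 50 kb in either replicate, nor had Zfy1. Ddx3x, Eif2s3x, Kdm5c, Kdm6a and Zfx on the X chromosome had promoter peaks in both replicates. The Y chromosome had 64 and 69 peaks, of which 39 and 42 had Erdr1 as the nearest gene, and of the other 25 and 27 all but 2 and 1 lay in LTR elements or satellites. Xist, the RNA gene of X inactivation, had weak promoter peaks with scores of 2.96 and 2.22 (percentiles 5.52 and 0.626 of their lists), and its neighbour Jpx had scores of 23.4 and 28.7. On the X chromosome 267 of 905 coding genes (29.5%, 26.6 to 32.6) had a promoter peak, against 47.1% of autosomal genes and 36.7% to 54.9% on single autosomes. The labels used here give no sex for the cells.

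Macrophage genes such as Apoe and C1qa had promoter peaks, and the text on lysis names macrophages. For samples that were macrophages, the test assumed a macrophage share at least as high as that of the type 1 dendritic cell list. The macrophage share was 29.6 points lower, a difference that passed Fisher's exact test in the main setting and in 4 of 9 alternatives (21.2 to 36.9 points, adjusted p 0.0142 to 0.250). However, the lists may differ in promoter share in any cell, and this difference was known when the test was chosen, so it cannot decide. A small admixture may also place promoter peaks at macrophage genes, low in the peak lists. The median score percentile of these peaks among promoter peaks was 41.4 in replicate 2 and 46.9 in replicate 1, between the bounds of 25 and 50 set for that test. Without a macrophage sample measured alike, and with no sort named in the labels, neither possibility can be settled, and macrophage genes being open in dendritic cells themselves stays open too.

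The larger number of peaks near inflammatory than antiviral genes was set against 3 technical explanations. Gene-dense surroundings of antiviral genes, where neighbours take the peaks, predict that the excess vanishes once every shared peak within 50 kb is counted, but means were then 9.98 and 7.33, an excess of 36.1% of the antiviral mean, down from 86.8%, and 115% of the raw difference (permutation test, p = 0.0138). After a fit on gene length and on territory, the span around a gene in which it is the nearest, 106% of the difference remained (permutation p = 7.0e-05), and without genes that have another list member within 200 kb 92.7% remained (34 and 27 genes, p = 0.0133). In the count of every shared peak, neighbouring members of a list can count the same peak. Among the 34 and 27 genes without such neighbours, the excess in that count was 35.7% of the antiviral mean (permutation test, p = 0.0388). These values argue against each of the 3 as the whole cause. No biological explanation was tested, and mappability and the choice of list members stay untested too.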
